A study of Mus musculus with 4 samples.

How the data were processed

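RNA of mouse C3H10T1/2 cells, a mesenchymal line from C3H embryos that can form several connective tissue cell types, was sequenced in 4 libraries. The cells stably expressed histone H3.3 with a FLAG-HA tag, either wild type (WT, 2 libraries) or carrying the lysine-to-methionine substitution K36M (2 libraries). Per the labels, cells grew in serum-supplemented DMEM, RNA was taken with Trizol and libraries were made by the Illumina TruSeq protocol. Whether RNA was selected by its poly(A) tail and whether libraries kept strand is not given in the sources used here. Each library's group and replicate number came from its title. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

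The deposited matrix holds RSEM expected counts, estimated read numbers that need not be whole, for 20325 gene symbols in each library. Per the submitters' processing notes, reads were handled with Bowtie 1.0.0 and RSEM 1.2.12 on the mouse build mm9, and per the file headers the expected counts were used by the authors for EBSeq. A second deposited table lists 594 genes with a log2 value per library and a fold change. Its log2 values, deposited by the authors, equal log2 of the expected count times 1 factor per library plus 1, with a largest difference of 5e-09. The authors' fold is a linear ratio of group means of the unlogged values, K36M over WT, checked to a relative difference of 4.9e-15. What chose those 594 genes, beyond a ratio over 10 or under 0.1, is not given in the sources used here. The factors were 1.35 and 1.46 for WT and 0.553 and 0.915 for K36M.

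Library totals were 25322433 and 23343297 expected counts in WT replicates 1 and 2, and 56041798 and 34022137 in K36M replicates 1 and 2. A floor of 3 counts corresponds to 0.121, 0.13, 0.0528 and 0.0863 CPM (expected counts scaled to a common library size) in these libraries, and to 0.0628 and 0.0328 CPM over both WT and both K36M libraries. A fold against a group at 0 counts was computed against that group floor and is a lower bound. For genes with 1 to 3 counts in a group the ratio carries a 95% interval (Clopper-Pearson on the 2 group counts, scaled by depth). Intervals and floors cover counting error only, since reads were counted without molecular identifiers.

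The design set before the data were examined gave a count model if the matrix held counts or expected counts, and that branch was used. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: low-count genes removed by filterByExpr, TMM scaling, a quasi-likelihood F test of K36M against WT with 2 residual degrees of freedom, and Benjamini-Hochberg adjustment over the 13162 genes left. The F test also drew on the spread of other genes, which added 15.7 prior degrees of freedom. The common coefficient of variation between libraries of a group, beyond counting error, was 3.33%. A gene is called changed at an adjusted p under 0.05. CPM use the TMM effective library sizes, and values are mean ± SD over n = 2 libraries unless stated. The replicate number did not enter this fit. On counts simulated for this comparison, with 13056 genes tested, the test recovered 36 of 50 genes at the smallest fold simulated, 72% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold. It made 175 calls there, of which 5 were false. Only 50 genes were changed at each fold, rising and falling in equal numbers. All genes were drawn independently with a common dispersion, so these rates need not hold in the data.

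Before the data were examined, 34 gene lists were fixed: adipogenic, osteogenic, chondrogenic, mesenchymal progenitor, smooth muscle and contractile, skeletal muscle, Wnt ligands, Wnt targets and inhibitors, Hox genes, other developmental regulators often held by Polycomb repressive complex PRC2, H3K36 writers, readers and erasers, Polycomb subunits and H3K27 demethylases, S phase, G2 and mitosis, interferon response, germline genes sensitive to DNA methylation, imprinted genes, TGF-beta and BMP response, Hedgehog and Notch, collagens and matrix, matrix proteases and inhibitors, cytokines and chemokines, p53 targets and senescence, endoplasmic reticulum and integrated stress, cholesterol synthesis, glycolysis and hypoxia, immediate early genes, protocadherin and axon guidance, ribosomal proteins, mitochondrial-encoded genes, and markers of 4 other cell sources (blood and macrophage, epithelium, endothelium, neural and glia). Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 33 lists with at least 5 tested members. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. On simulated counts camera called the list that had been moved and 0 of 30 random lists. Genes were drawn independently there, so this does not show how camera behaves on lists of correlated genes. Members not in the matrix were not analysed here, among them all 9 mitochondrial-encoded genes.

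Genes are named by a rule set at the same time: H3f3a and H3f3b, the 10 genes with the largest fold change each way among called genes whose 2 libraries of 1 group both lie beyond both of the other with at least 5 CPM in the higher group, up to 4 members of each list by smallest p, and Wnt6, Sox6, Sox9, Runx2, Pparg, Cebpa, Nsd2 (Whsc1 in the matrix), Setd2 and Ezh2. Other names are said to be chosen after their values were seen. Counts of near-identical genes (histones, Sprr2a and protocadherin clusters, among others) depend on how RSEM divided shared reads. Among genes with more than 10 counts in every library, 10 had values equal to those of another gene in all 4, and 3066 genes had 0 counts in all libraries.

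Alternatives were a replicate block, leaving out each library in turn, no low-count filter, a filter at a mean of 5 CPM, DESeq2 size factors, upper quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom, a 2-fold requirement and an adjusted p of 0.1. Scaling by the authors' factors, scaling by total counts, thinning of all libraries to the smallest total in 10 draws and glmTreat against 2-fold were added after seeing the data. Pseudocount alternatives applied only to normalized units and were not run. For the closing section, 99.4% of tested genes were given a chromosome and 99.2% a transcript length and GC content from RefSeq on GRCm38 and GENCODE release M21, which differ from the build of the files, so no coordinates are printed. Python 3.11.15 and BLAST 2.17.0 were used there.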

Results

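Expression was measured by RNA sequencing in C3H10T1/2 cells expressing H3.3 WT (n = 2) or H3.3 K36M (n = 2). The comparison asks which genes and lineage programs differ between mesenchymal cells with the mutant histone, an inhibitor of H3K36 methyltransferases, and cells with the wild type histone. Totals ranged from 23343297 to 56041798 expected counts, and the K36M libraries were 1.85 times as deep as the WT libraries on average. Replicates correlated at r = 0.995 within WT and 0.997 within K36M over log2 CPM of genes, against 0.894 to 0.896 between groups. Counts of the 2 libraries of a group differed by more than counting noise (mean chi-square per gene 3.68 in WT and 7.41 in K36M on 1 degree of freedom), so neither pair is 1 library deposited 2 times; repeats of 1 culture can differ as much.

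The H3.3 genes themselves were lower in the K36M cells. H3f3a stood at 694 and 687 CPM in the WT libraries and at 388 and 409 CPM in the K36M libraries, 1.73-fold lower (adjusted p = 5.78e-13). H3f3b stood at 1019 and 981 CPM in WT and at 812 and 844 CPM in K36M, 1.21-fold lower (adjusted p = 3.21e-06). Whether reads of the tagged transgene were counted on these genes is not given in the sources used here, so these values do not check the labels.

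Most cartilage genes fell in K36M cells, with 20 of 22 chondrogenic genes at least 2-fold lower, and of 37 collagen and matrix genes 30 fell, 17 of them at least 2-fold. More genes rose than fell among S phase, G2 and mitosis, ribosomal protein, contractile and cytokine genes. Camera called all of these lists at a preset correlation between genes and none of them with an estimated correlation (adjusted p = 0.390 to 0.847). The estimated-correlation test rests on 2 residual degrees of freedom and has little power, so a lost call there need not come from correlated genes. The collagen and matrix list lost its call with an estimated correlation of -0.015, below the preset 0.01. The chondrogenic and the G2 and mitosis lists had 0.634 and 0.579. Sox9, the master regulator of cartilage formation, fell from 492 ± 14.5 to 70.8 ± 2.74 CPM, and its partner Sox6 from 96.3 ± 6.25 to 0.857 ± 0.0909 CPM. Eln, which encodes elastin, fell from 1046 ± 48.9 to 2.78 ± 0.467 CPM. In the other direction Stra6, the receptor for retinol-binding protein, rose from 0.186 ± 0.079 to 55.7 ± 1.51 CPM, and Ccl2, a monocyte chemokine, from 0.832 ± 0.193 to 28.6 ± 1.14 CPM. Of 13162 genes tested with edgeR, 9949 (75.6%) passed an adjusted p of 0.05, 5070 higher and 4879 lower in K36M. Most of these differences were small, 5475 of them under 1.5-fold. At least 2-fold changes numbered 1665 higher and 1144 lower, and at least 10-fold changes 561 higher and 224 lower. Scaled by the authors' factors, 4360 genes were higher and 5709 lower at an adjusted p under 0.05, so the balance of all calls depends on scaling.

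**Figure D1:**
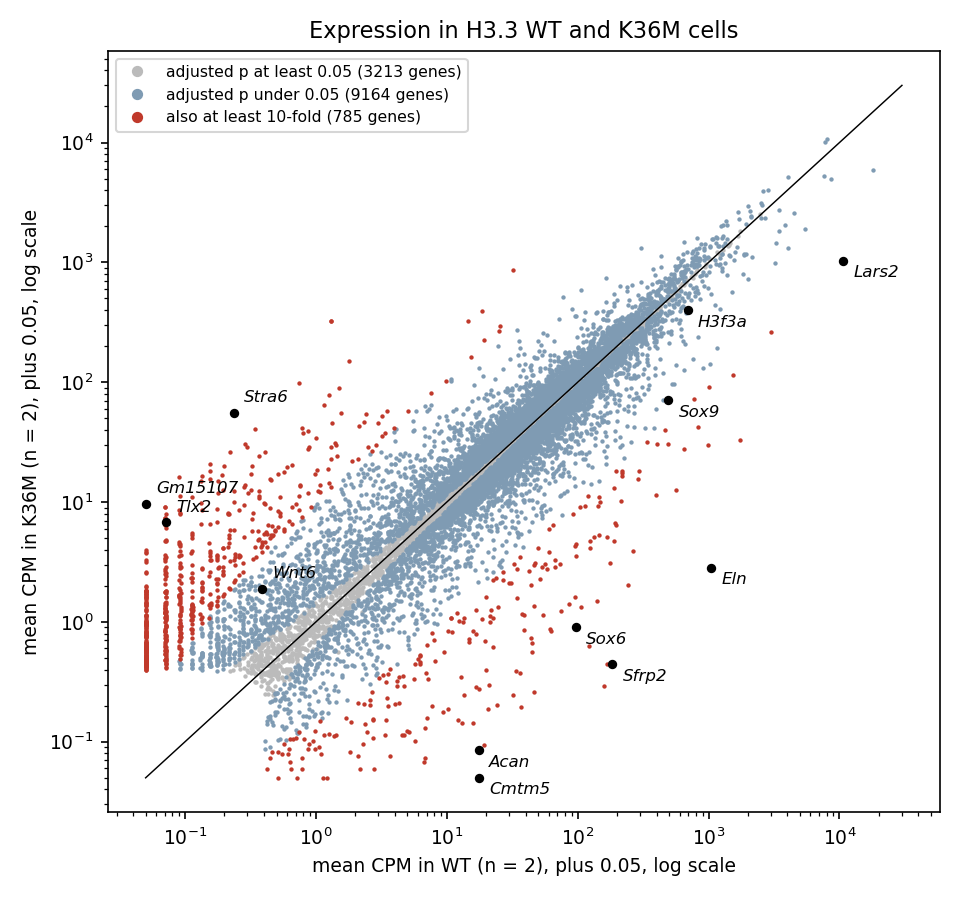
Mean CPM of each tested gene in WT (x axis) and K36M (y axis), n = 2 libraries each, with 0.05 added, on log axes; the diagonal marks equal expression and colours give the edgeR call. Eln, Sfrp2, Sox6 and Acan lie far below the diagonal, Stra6, Tlx2 and Gm15107 far above it, and Lars2, labelled after its values were seen, is the abundant gene at the right.

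Among the 10 genes with the largest falls, Cytl1, which encodes a secreted chondrocyte factor, was 432-fold lower, Eln 386-fold lower and Acan, the aggrecan gene, with 4 counts in K36M, 370-fold lower. Sfrp2, a secreted Wnt modulator, was 489-fold lower, and C1qtnf3, a secreted cartilage factor, 237-fold lower. Cmtm5 had 837 counts in WT and 0 in K36M, at least 534-fold lower, and Gm5886 was 651-fold lower. Angptl1, with 3 counts left in K36M, had a counting interval of 198-fold to 2820-fold. Glt25d2 (84.9-fold to 2560-fold) and Bbox1 (82.8-fold to 2500-fold) had 2 counts each left. Every adjusted p of these 10 genes was at or below 9.67e-14 and all 4 libraries were separated by group.

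Several of the 10 largest rises were of genes hardly detected in WT. Gm15107 had 0 counts in WT and 855 in K36M, at least 154-fold higher. Stra6 was 291-fold higher, and Sprr2a2, a small proline-rich protein of epithelial barriers whose counts equal those of its copy Sprr2a1, 264-fold higher. F13a1, a subunit of coagulation factor XIII, had 1 count in WT and 820 in K36M (counting interval of the ratio 76.6 to 16900). The same held for Fcgbp (77.8 to 17200), Apob, the apolipoprotein B gene (61.5 to 13600), Eda, the ectodysplasin ligand (63.5 to 14000), Tlx2, a homeobox gene (57.6 to 12700), C130026I21Rik (67.0 to 14800) and 3830417A13Rik (106 to 3170), each with 1 or 2 counts in WT.

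Of the lineage programs, the chondrogenic one moved furthest. Of 22 tested chondrogenic genes 20 fell and 0 rose, with a median log2 fold change of -3.69. Besides Sox9, Sox6, Cytl1 and Acan, the fibrillar collagen gene Col11a1 fell from 1536 ± 29.9 to 114 ± 5.12 CPM, Col9a1 from 146 ± 1.02 to 5.24 ± 0.442 CPM, and Lect1, the chondromodulin gene, from 142 ± 6.84 to 1.46 ± 0.14 CPM. Matn2 (log2 fold change -0.05) and Prg4 (-0.16), named after their values were seen, did not pass the test. The list was called lower by camera (adjusted p = 5.73e-29), and had adjusted p = 0.520 with an estimated correlation of 0.634 between its genes.

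**Figure D2:**
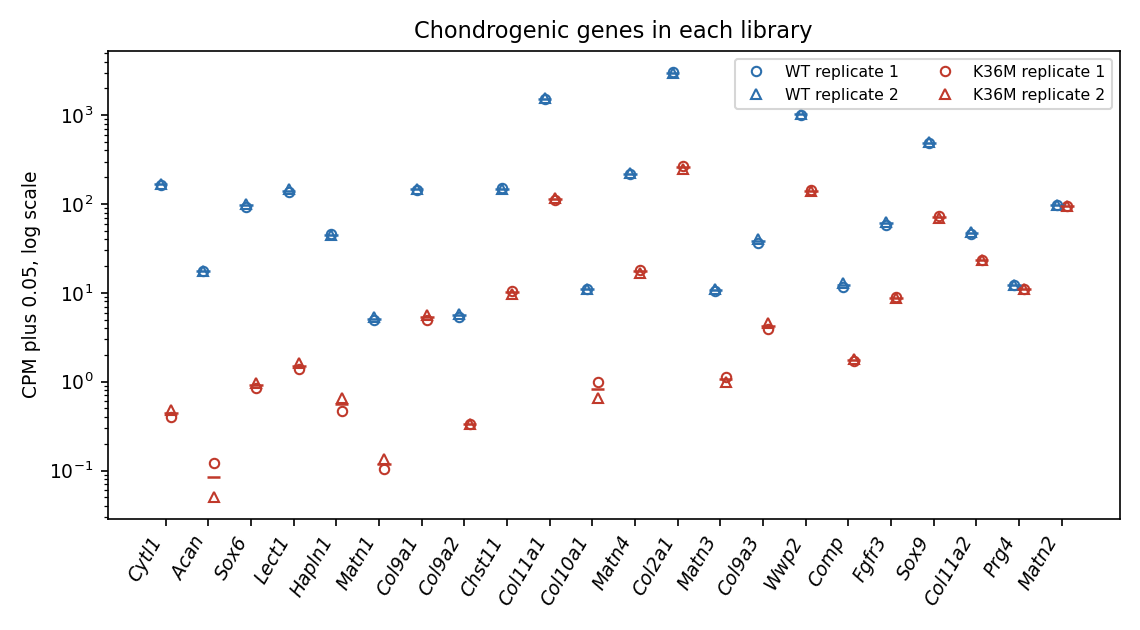
CPM of the 22 tested chondrogenic genes in each library, with 0.05 added, on a log axis; circles and triangles are replicates 1 and 2, horizontal bars group means (n = 2), and genes are ordered by log2 fold change. In 20 genes both K36M libraries lie below both WT libraries by more than the replicates differ, from Cytl1 at the left to Col11a2, while the groups of Prg4 and Matn2 at the right nearly coincide.

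Genes of fat and bone formation changed in both directions. The adipogenic transcription factors Pparg (28.7 ± 0.541 to 12.1 ± 1.03 CPM) and Cebpa (53.6 ± 2.57 to 9.30 ± 0.202 CPM) fell, as did Cebpd, the lipid droplet gene Plin4 and the preadipocyte gene Dlk1, with log2 fold changes of -1.55, -1.02 and -1.90, while Cebpb (0.32), Srebf1 (0.59) and Klf5 (2.33), named after their values were seen, rose. Of 21 adipogenic genes 7 rose and 10 fell (median -0.32), and the list was not called (adjusted p = 0.118). The bone regulator Runx2 was 1.12-fold lower (adjusted p = 0.0066), and not past the threshold without WT replicate 2 (adjusted p = 0.066). Tnfrsf11b, which encodes osteoprotegerin, fell 33.6-fold, the parathyroid hormone receptor gene Pth1r 12.7-fold and Msx1 3.78-fold, while Spp1, the osteopontin gene, rose 4.25-fold. Of 20 osteogenic genes 5 rose and 12 fell (median -0.32, adjusted p = 0.127).

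Most genes of contractile cells rose. Actg2 rose 9.96-fold, Myl9 4.16-fold, Tpm2 3.88-fold and Cnn2 from 211 ± 8.12 to 635 ± 1.67 CPM, and 9 of 14 smooth muscle and contractile genes rose while 3 fell (median 0.62, adjusted p = 0.000885). With an estimated correlation the adjusted p was 0.520. Acta2 and Cald1, abundant members named after their values were seen, fell, with log2 fold changes of -0.39 and -0.24. Among mesenchymal progenitor genes the adhesion molecule Alcam rose from 18.5 ± 1.11 to 393 ± 8.06 CPM, and Thy1, Nes and Prrx2 rose 11.2-fold, 2.62-fold and 1.89-fold. Of the 22, 11 rose and 9 fell (median 0.13), and the list lay just beyond the threshold (adjusted p = 0.0505), past it without WT replicate 1 (0.0184), without WT replicate 2 (0.0158) and without K36M replicate 2 (0.0141), but not without K36M replicate 1 (0.0922). It was also past it under upper quartile scaling (0.0107), total counts (0.0108), the authors' factors (0.0179), a mean of 5 CPM (0.00956) and thinning (0.00985), but not with DESeq2 size factors (0.0982), limma-voom (0.248) or no low-count filter (0.233). Skeletal muscle genes were weak, with Acta1 at 4.73 ± 0.07 and 10.7 ± 0.619 CPM, Chrna1 2.36-fold higher, and Ttn not past the threshold (adjusted p = 0.0624), but past it without K36M replicate 2 (0.0094), with no low-count filter (0.0386) and under total counts (0.0463). Of those 7, 3 rose and 0 fell (median 0.90, adjusted p = 0.544). Tnnc2 (log2 fold change 0.90, adjusted p = 0.0288) stayed higher (0.39 to 0.89) but was not past the threshold without WT replicate 1 (0.393) or K36M replicate 1 (0.126), with the DESeq2 Wald test (0.173) and in a thinned draw (0.0608).

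Most matrix genes fell. Thbs1, the thrombospondin-1 gene, fell 11.2-fold, Col8a1 18.5-fold and Postn, the periostin gene, 10.6-fold. Of 37 collagen and matrix genes 30 fell and 7 rose (median -0.96, adjusted p = 9.57e-14), with adjusted p = 0.390 with an estimated correlation. Col1a1, an abundant member named after its values were seen, rose (log2 fold change 0.40, adjusted p = 3.44e-06). Of 18 matrix proteases and inhibitors 6 rose and 9 fell, and the list was not called (adjusted p = 0.105), though it was without K36M replicate 2 (0.0407) and at a mean of 5 CPM (0.0199). Its median was -0.19 and its mean 0.20, so these differ in sign. Adamts1 fell 4.01-fold, Adamts12 7.49-fold, Adamts5 1.78-fold and Timp3, an inhibitor of matrix metalloproteinases, from 4037 ± 53.1 to 1316 ± 13.4 CPM.

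Several Notch pathway genes fell. Notch1 fell 7.97-fold, its ligand gene Jag1 5.80-fold, and the Notch target genes Hey1 24.0-fold and Hey2 119-fold, while Notch3 and Jag2, named after their values were seen, rose (log2 fold changes 1.19 and 1.75). Of 18 Hedgehog and Notch genes 13 fell and 5 rose (median -0.57, adjusted p = 0.00496), with adjusted p = 0.520 with an estimated correlation. Of 8 Wnt ligands 5 rose and 1 fell (median 1.61, adjusted p = 0.255). Wnt6 was 5.54-fold higher at 1.85 ± 0.173 CPM, Wnt9a 5.54-fold, and Wnt7b 5.17-fold higher, Wnt5a rose from 8.27 ± 0.573 to 14.8 ± 0.697 CPM, and Wnt5b fell 2.51-fold. Of 18 Wnt targets and inhibitors 13 rose and 4 fell (median 1.36, adjusted p = 0.0981). Notum, a secreted Wnt inhibitor, rose 20.4-fold, while the Wnt transcription factor gene Tcf7 fell 7.56-fold, Wisp2 3.89-fold and Sfrp2 as above. Of 25 TGF-beta and BMP response genes 11 rose and 12 fell (median -0.14, adjusted p = 0.842), with Tgfb2 11.5-fold lower and the BMP antagonist Grem1, the latent TGF-beta binding gene Ltbp1 and Tgfbi 10.7-fold, 3.39-fold and 5.16-fold higher.

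Most cytokine and chemokine genes rose. Ccl2 rose 33.9-fold, the prostaglandin synthase gene Ptgs2 9.96-fold, the interleukin-33 receptor gene Il1rl1 8.16-fold and the macrophage growth factor gene Csf1 2.77-fold. Of 19 such genes 14 rose and 2 fell (median 1.47, adjusted p = 1.24e-05), with adjusted p = 0.520 with an estimated correlation. Interferon response genes went both ways, 13 of 27 higher and 8 lower (median 0.36, adjusted p = 0.483). Bst2 rose 4.28-fold and Trim30a 59.7-fold, while Ifit3 fell 3.14-fold. Of 19 immediate early genes 11 rose and 4 fell (median 0.30, adjusted p = 0.358), with Fosl1 8.28-fold and Dusp1 2.08-fold higher and Nr4a1 2.46-fold and Klf4 1.52-fold lower.

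Most genes of proliferating cells rose by small amounts. Of the replication licensing genes Mcm2 rose from 80.4 ± 2.77 to 176 ± 7.56 CPM and Mcm7 and Cdt1 1.75-fold and 2.13-fold, and Uhrf1 1.99-fold. Of 25 S phase genes 23 rose and 0 fell (median 0.57, adjusted p = 1.24e-05), with adjusted p = 0.541 with an estimated correlation. Top2a, Aurkb, Birc5 and Bub1 rose 1.85-fold, 1.57-fold, 1.40-fold and 1.40-fold, and of 25 G2 and mitosis genes 20 rose and 2 fell (median 0.26, adjusted p = 0.0133). The adjusted p was 0.847 with an estimated correlation, 0.148 without WT replicate 2, 0.0936 under the authors' factors and 0.0516 in a thinned draw. All 30 ribosomal protein genes rose (median 0.45, adjusted p = 4.58e-07), with adjusted p = 0.541 with an estimated correlation, and 28 rose under the authors' scaling. Among them Rps14, Rpl23, Rpl19 and Rpl32 rose 1.60-fold, 1.63-fold, 1.56-fold and 1.49-fold. Of 20 endoplasmic reticulum and integrated stress genes 14 rose and 2 fell (median 0.31, adjusted p = 0.0023), with adjusted p = 0.555 with an estimated correlation. The stress factors Nupr1, Ddit3 and Atf5 rose 3.89-fold, 1.79-fold and 1.59-fold, and the serine synthesis gene Psat1 2.64-fold.

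The p53, cholesterol and glycolysis lists were not called (adjusted p = 0.747, 0.688 and 0.747). Of 16 p53 targets 9 rose and 7 fell. Phlda3, Perp and Sesn1 fell 3.41-fold, 4.63-fold and 2.08-fold while Ccng1 rose 1.75-fold, and the list's median (0.24) differs in sign from its mean (-0.17) and its test. Of 23 cholesterol synthesis genes 5 rose and 12 fell (median -0.10, mean 0.11), with Hsd17b7 falling from 84.8 ± 0.0603 to 47.1 ± 1.17 CPM, Pmvk 1.87-fold lower and Insig1 1.40-fold higher. Of 23 glycolysis and hypoxia genes 11 rose and 9 fell (median 0.05), with Gpi1 and Pfkp 2.46-fold and 2.27-fold higher and Pdk1 and Slc2a1 4.54-fold and 1.89-fold lower.

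Homeobox and other developmental regulators changed in both directions. Hoxb9 rose from 0.106 ± 0.0351 to 20.8 ± 1.3 CPM, while Hoxc13 fell from 18.4 ± 1.37 to 0.998 ± 0.108 CPM, Hoxa3 3.43-fold and Hoxa2 2.04-fold. Of 18 Hox genes 8 rose and 7 fell (median -0.03, mean 2.37, adjusted p = 0.864), and 5 members had 0 counts in 1 group. Of 40 other developmental regulators often under PRC2 16 rose and 16 fell (median 0.01, mean -0.30, test lower, adjusted p = 0.483). Osr2 rose 11.7-fold, and Sall1 and Osr1 fell 10.4-fold and 2.36-fold. Of 31 protocadherin and axon guidance genes 16 rose and 14 fell (median 0.82, adjusted p = 0.747), with Sema5a and Sema3a 10.8-fold and 5.87-fold higher and Unc5c and Slit3 10.9-fold and 31.9-fold lower.

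Genes of chromatin enzymes changed in both directions. Nsd2 (Whsc1), an H3K36 dimethyltransferase gene, rose from 83.8 ± 0.613 to 174 ± 0.162 CPM, and Setd2, the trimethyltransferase gene, was 1.18-fold lower. Psip1, which encodes an H3K36 methylation reader, rose 1.48-fold, and Kdm4b and Morf4l1 fell 1.65-fold and 1.35-fold. Of 22 H3K36 writers, readers and erasers 5 rose and 11 fell (median -0.10, adjusted p = 0.764). Ezh2, the PRC2 methyltransferase gene, was 1.13-fold lower (adjusted p = 0.00437), and not past the threshold without WT replicate 1 (adjusted p = 0.0801). Suz12, Pcgf5 and Cbx2 rose 1.74-fold, 3.13-fold and 1.56-fold, and Rnf2 fell 1.57-fold. Of 29 Polycomb subunits and H3K27 demethylases 9 rose and 10 fell (median -0.06, mean 0.07, adjusted p = 0.783).

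Imprinted genes were divided, with 7 of 16 higher and 7 lower (median 0.31, adjusted p = 0.864). Peg3 rose 72.1-fold, Plagl1 6.25-fold and the growth factor gene Igf2 8.33-fold, while the receptor gene Igf2r fell 1.76-fold. Germline genes stayed near detection, with 3 of 7 lower and 0 higher (median -0.50, adjusted p = 0.688). Ddx4 was 5.36-fold lower at 1.36 ± 0.0176 CPM in WT, and Piwil2 did not pass the test (adjusted p = 0.186). Sycp2 and Sycp3 (log2 fold changes -0.91 and -0.84, adjusted p = 0.00603 and 0.0135) stayed lower by similar amounts (-0.90 to -0.78 and -0.83 to -0.65) but were not past the threshold without WT replicate 2 (0.0643 and 0.114) and without K36M replicate 1 (0.0541 and 0.136) and with the DESeq2 Wald test (0.0838 and 0.134), nor was Sycp3 in a thinned draw (0.074).

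Some markers of other cell types differed between the groups. Camera called none of these 4 lists. Fry called blood and macrophage (adjusted p = 0.00449) and epithelium (0.0212) higher and endothelium (0.00449) lower. Hba-a1, an alpha globin gene, rose from 0.171 ± 0.127 to 26.0 ± 0.995 CPM, and of 7 blood and macrophage markers 5 rose and 1 fell (median 1.37, adjusted p = 0.146). Lyz2 and Cd14 rose 3.56-fold and 1.57-fold and Fcgr1 fell 2.76-fold. E-cadherin (Cdh1) rose 4.04-fold and Krt8 5.97-fold, Krt14 fell 7.44-fold, and Esrp1 went from 0 to 44 counts, at least 8.04-fold higher. Of 6 epithelial markers 5 rose and 1 fell (median 2.29, adjusted p = 0.471). Of 5 endothelial markers 2 rose and 2 fell (median 0.09, mean -1.28, adjusted p = 0.435), with Erg falling from 17.5 ± 0.918 to 0.223 ± 0.0915 CPM, Tek 5.91-fold lower, and Flt1 and Cdh5 1.69-fold and 3.22-fold higher. Of 6 neural and glial markers 3 rose and 3 fell (median 0.12, adjusted p = 0.726). Tubb3 and Stmn2 rose 1.92-fold and 3.98-fold, and Dcx had 1 count in WT and 54 in K36M (ratio interval 4.85 to 1130).

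**Figure D3:**
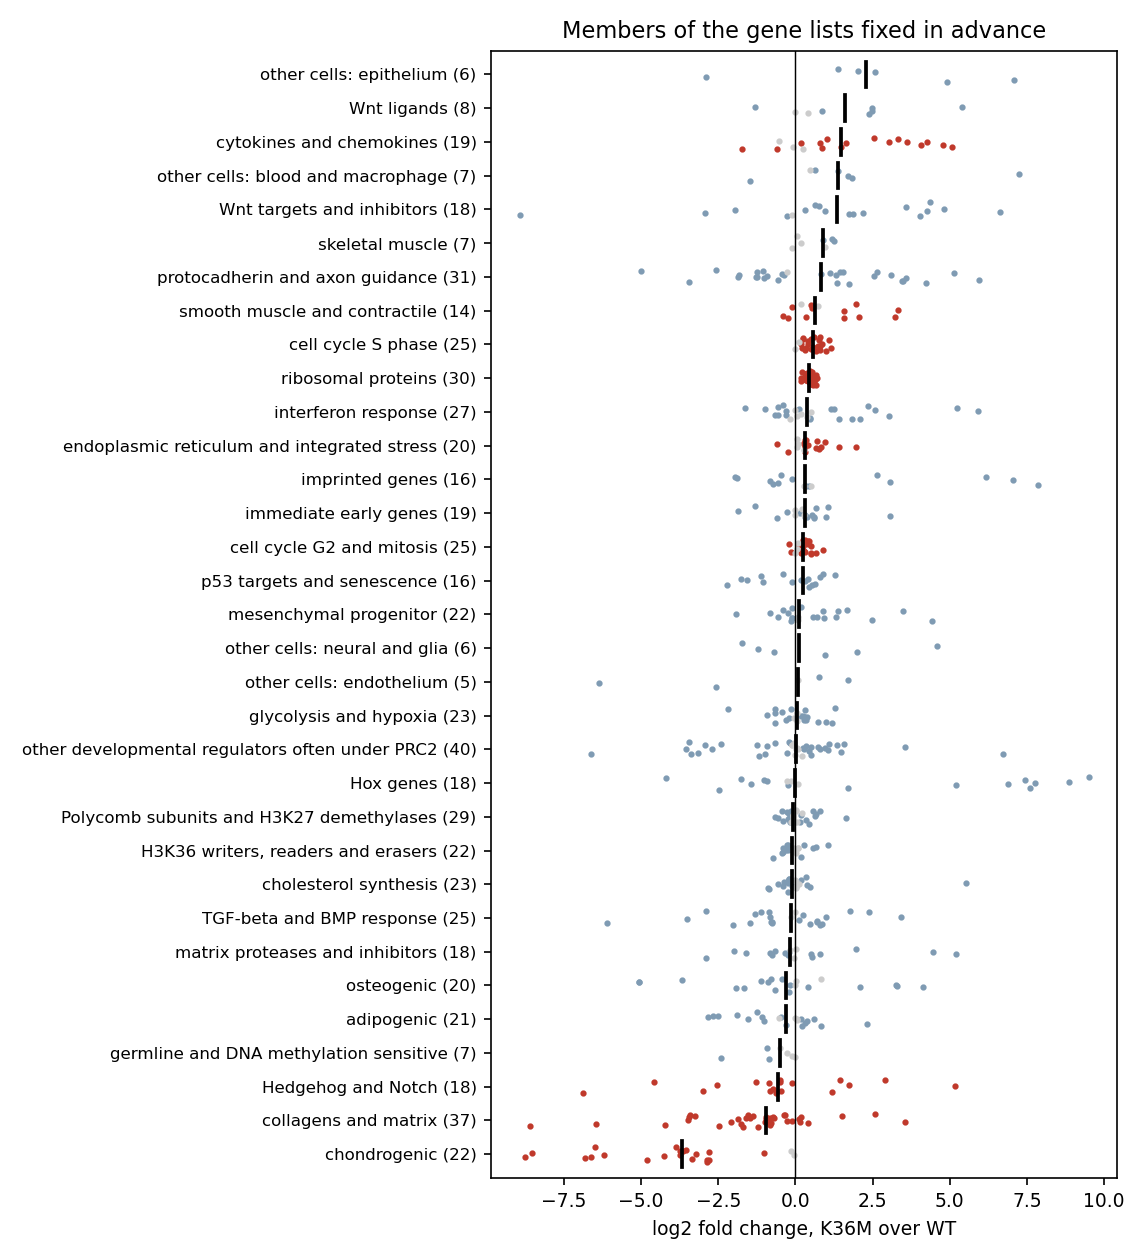
Log2 fold change, K36M over WT, of every tested member of the 33 tested lists, whose number of members stands in brackets; black bars are medians, grey points did not pass an adjusted p of 0.05, and red lists were called by camera at the preset correlation. The chondrogenic list at the bottom has its median at -3.69, and the S phase and ribosomal protein lists form narrow groups right of 0.

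At the preset correlation camera called 9 of the 33 lists, 3 lower and 6 higher. With an estimated correlation, which rests on 2 residual degrees of freedom, it called 0, the smallest adjusted p being 0.390, and 2 lists had an unadjusted p under 0.05. With so few degrees of freedom this test could call few lists, whatever their correlation. Fry called 26. Counts of members adjusted over the list alone equalled those above for 31 lists and differed for mesenchymal progenitor genes (12 higher) and blood markers (6 higher). None of the mitochondrial-encoded genes was in the matrix.

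The authors' deposited table of differential genes holds 594 genes, 385 higher and 209 lower in K36M, all beyond 10-fold. Of these, 591 were tested here and all 591 were called in the same direction, which is not independent since the table came from the same libraries. Applying the formula of the authors' deposited table to the whole matrix gave 773 genes beyond 10-fold, of which 179 are not in it, 170 of them higher in K36M.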

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

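Thinning, the authors' factors, total counts and glmTreat were chosen after the data were seen. Depth limited the weakly expressed genes most: 3 counts in a WT library correspond to 0.121 or 0.13 CPM. The cause of the differences below was not tested, except that a stricter filter and a fold requirement remove genes by construction. No setting changed the sign of a gene named by the rule, where that setting tested it. Genes named after their values were seen were not compared over settings. Genes at least 10-fold higher numbered 943 with no low-count filter and 103 at a mean of 5 CPM or more, where 131 were at least 10-fold lower, 1260 changed at least 2-fold and 228 overlapped the authors' deposited table. Requiring 2-fold left 2809 changed genes, 1665 higher and 1144 lower, and glmTreat left 2190, 1304 and 886. The share of calls that were higher was 51% in the reported fit, 43.3% under the authors' factors and 55.9% under total counts, and the median of all tested genes was 0.00347, -0.0829 and 0.0535 in these 3 fits.

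With the replicate number as a block, 9804 genes were called, 9771 of them shared in direction with the 9949 of the fit without it. The labels do not say that the numbers pair the samples, and deviations of same-numbered libraries correlated at r = 0.0026. The block brought in the mesenchymal progenitor list (adjusted p = 0.0151) and changed no other list or named gene. Leaving out each library in turn gave 9128 to 9953 changed genes and chondrogenic medians of -3.71 to -3.56.

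Lists called numbered 0 with an estimated correlation, where the chondrogenic median of -3.69 had an adjusted p of 0.520, and 26 with fry. Thinned to equal totals the chondrogenic median was -3.76 to -3.59. The G2 and mitosis list, with medians of 0.17 and 0.26, was not called under the authors' factors (adjusted p = 0.0936) and in a thinned draw (0.0516). Medians near 0 of uncalled lists changed sign: PRC2-held regulators (leave-one-out -0.041 to 0.023, authors' factors -0.079, thinned -0.065), Polycomb subunits (-0.059 to 0.002 leave-one-out), endothelium (-0.011 to 0.167 leave-one-out), Hox genes (1.26 unfiltered, 0.013 upper quartile, 0.022 total counts), glycolysis (-0.032 authors' factors) and neural markers (-0.025 thinned). The germline median, further from 0, went from -0.503 to 0.018 unfiltered. At a mean of 5 CPM other uncalled lists had medians of the opposite sign: adipogenic (-0.320 to 0.049), interferon (0.364 to -0.279), imprinted (0.306 to -0.264) and TGF-beta (-0.137 to 0.153). The protocadherin and axon guidance median went furthest, from 0.818 to -0.428.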

Other observations

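Groups of genes outside the comparisons above, and genes named in this part, were chosen after their values were seen. Tested Hox genes lay in 3 clusters, which were not tested against each other. All 7 tested Hoxb genes rose, from 0.149 CPM summed over the cluster in WT to 28.4 CPM in K36M, and 5 of them had 0 counts in WT. Those 5 could pass the low-count filter only through the K36M libraries, so their direction was fixed by that filter. Hoxb9 alone stood at 20.8 CPM in K36M. Of 8 tested Hoxa genes 0 rose and 5 fell, with a summed level of 108 CPM in WT and 59.0 CPM in K36M, and of 3 Hoxc genes 1 rose and 2 fell. In the gamma protocadherin cluster 17 of 22 tested genes fell and 0 rose (median log2 fold change -0.65), while of 20 beta protocadherin genes 6 rose and 11 fell. As families, neither Hoxa nor beta protocadherin genes (adjusted p = 0.403 each) nor the 12 tested gamma A protocadherin genes (0.531) were called. Gamma genes share exons, so their separate counts are uncertain, and their summed level was 954 CPM in WT and 683 CPM in K36M.

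Families formed by symbol stem numbered 204, and some stems take in other genes, such as the kinase gene Rps6ka1 in Rps and Col4a3bp in Col. Camera at the preset correlation called 5 of them: Col and Hist lower, Rpl, Rps and Mcm higher. All but Hist share members with the lists fixed in advance and are no separate support for them. None was called with an estimated correlation (smallest adjusted p = 0.981). Genes of the Hist stem were taken as replication-dependent by symbol alone. They stood out because such genes are expressed in S phase, whose genes rose: 38 of 53 tested fell and 2 rose (median log2 fold change -1.26, adjusted p = 0.00411). Hist1h1c fell from 277 ± 6.29 to 81.2 ± 0.42 CPM and Hist1h2bc from 150 ± 8.23 to 50.9 ± 0.273 CPM (n = 2). Hist1h3a, the most abundant in K36M, rose from 199 ± 6.87 to 230 ± 25.4 CPM (edgeR adjusted p = 0.00231). Hist1h3b, at 155 ± 0.475 CPM in WT and 147 ± 1.46 CPM in K36M, did not pass the test (adjusted p = 0.0753). Of 11 replacement-type histone genes 6 rose and 2, H3f3a and H3f3b, fell (median 0.12).

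For the patterns weighed below, the tests of S phase, of the level of background reads, of GC content, length and level, and of the course along chromosomes were chosen after the result was seen. So were chromosomes 11 and 14 themselves and the rules that made the Lars2 and olfactory receptor tests void. The summed level of the histone genes also fell, with a log2 ratio of -0.73. Both K36M libraries (698 and 638 CPM) lay below both WT libraries (1085 and 1127 CPM). A shift of shared reads among near-identical copies would leave that sum unchanged, so it does not account for the summed fall. Hist1h1c and Hist1h2bc, which fell as above, carry much of the summed fall, so for the less abundant copies such a shift stays open. The S phase list had a median of 0.57, which argues against fewer K36M cells in S phase. The list gives RNA levels only, and no count of cells in S phase was analysed here. Most replication-dependent histone mRNAs lack a poly(A) tail, so more of this RNA in the WT libraries could give the same picture. That stays open, and whether the mRNAs of Hist1h1c and Hist1h2bc lack a tail was not examined here. Histone genes shifted by a median log2 ratio of only -0.134 between the K36M libraries, but a difference set by group cannot be told apart from K36M. A change in histone mRNA ending or decay in K36M cells was not tested. Lars2, at 12860 and 8506 CPM in WT and 1671 and 394 CPM in K36M, differed by a log2 ratio of -2.08 between the K36M libraries, and its 9 annotated transcripts had 0 matches of at least 100 bases at 90% identity among 361 ribosomal RNA-type transcripts, none as long as 28S ribosomal RNA, which leaves carryover of that RNA open.

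Whole chromosomes shifted in median log2 fold change, 16 of 20 past an adjusted permutation p of 0.05 over genes, which are not independent replicates. Chromosome 11 had the largest rise (median 0.26, 1075 genes, 59.3% higher and 19.5% lower) and chromosome 14 the largest fall (median -0.29, 441 genes, 22% higher and 58.3% lower), each with p = 1e-04, the smallest that 10000 permutations can give; all 4 pairs of a K36M and a WT library gave 0.24 to 0.26 and -0.30 to -0.27. After regression on GC content, transcript length and expression level these 2 medians were still at least 0.247 from 0. These properties thus do not account for the shift of these 2 chromosomes. Among genes changed under 2-fold the 2 medians were at least 0.224 from 0. A few strongly changed genes could hardly move a median over so many genes, so that value adds little. Over all chromosomes 14 were past the threshold after regression, 7 and 15 no longer (adjusted p = 0.272 and 0.0684), and the median of X went from 0.13 to -0.01 among genes changed under 2-fold. With the genes along each of the 2 chromosomes cut into 4 consecutive parts, every part was displaced in the same direction, by at least 0.213, but the choice of the 2 most extreme chromosomes made this nearly certain, so it decides nothing. Of the other chromosomes past the threshold, 3, 9, 13, 18 and X had parts of both signs (-0.18 to 0.006, -0.104 to 0.001, -0.21 to 0.06, -0.007 to 0.19 and -0.03 to 0.27). On 3, 9 and 18 the part of the other sign lay close to 0. The rest, 1, 2, 5, 7, 12, 15, 16, 17 and 19, had all parts of the same sign, such as -0.317 to -0.145 on chromosome 1 and 0.079 to 0.1 on chromosome 5. A different copy number in the 2 cultures and an effect of K36M over whole chromosomes both stay open, and no DNA measurement was analysed here.

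More genes were at least 10-fold higher (561) than lower (224) in K36M. Deeper K36M libraries and scaling do not account for this, as the ratio stayed at 2.18 or more in 10 thinnings to equal totals and at 2.36 or more under 4 other scalings. The excess lies among weakly expressed genes: with at least 5 CPM in the higher group there were 153 higher and 154 lower, a ratio of 0.994. Olfactory receptor genes, silent in most tissues, were meant to show background reads, but their sum (ratio 1.19, K36M over WT) was judged void because Olfr613 held 85.5% of it, although a ratio under 2 had been set beforehand as the mark of no background. The other 1118 summed to 2.22 and 2.78 CPM in WT and 13.5 and 14.1 CPM in K36M. Their smallest ratio of 4.845 passes the mark of background set beforehand for the whole sum. Genes with symbols starting Vmn, summed beside them, had a ratio of 0.965. Of these 328 genes only 13 and 14 had any count in the WT libraries, so few genes hold that sum too. In the deeper K36M libraries 54 and 52 of them had a count, so the ratio does not decide on background. The mean of the 1118 in K36M, 0.0123 CPM per gene, is 0.73% of the median level of the 10-fold higher genes. Background even over genes at that level is too low to produce that median, but gene length was not taken into account. An effect of K36M and another difference between the cultures both stay open and were not tested.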
